A study of Mus musculus with 2 samples.

How the data were processed

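The deposit holds splenic Tregs of mice treated with IL-2 bound to JES6-1 or with PBS, in 10 arms marked by hashtag antibodies and pooled into 1 droplet library, listed as 2 samples (RNA and hashtags). Per the labels, reads were aligned to mm10 and UMIs counted with Cell Ranger 7.1.0. The labels name different kit chemistries in different places, so the end of the transcript that was read is not stated with certainty. They do not describe how cells were filtered or assigned to arms. The deposited RNA and hashtag matrices hold raw UMI counts per gene or hashtag and cell. The deposited table of cells gives an arm, a cluster (12 clusters, resolution 0.75) and a hashtag margin score for each cell, under the column names of Seurat's HTODemux. All 13319 cells were deposited as single-hashtag cells, with at least 1001 genes and at most 4.99% mitochondrial UMIs each. Pairs of cells that share a hashtag cannot be found this way, and no doublet caller was run. The files list 55487 gene symbols, of which 30165 have a UMI. Sums per cell matched the deposited totals and arm names matched the hashtags for every cell when checked.

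Depth differed between arms. Total UMIs were 9232399 at 1 h, 595371 at 2 h, 11862734 at 4 h, 13125599 at 8 h, 15006460 at 16 h, 16017842 at 24 h, 20946655 at 64 h, 16284194 at 128 h, and 9362465 and 9715916 in the PBS arms at 2 and 128 h. The median UMIs of a cell's own hashtag were 1039 at 1 h, 14 at 2 h, 545 at 4 h, 648 at 8 h, 423 at 16 h, 466 at 24 h, 283 at 64 h and 245 at 128 h, and 576 and 749 in the PBS arms. Where intervals are given for values of single arms, they are exact 95% Poisson (CPM) or Clopper-Pearson (share) intervals.

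UMIs were summed per arm and all 10 arms fitted together in edgeR 4.0.16 (R 4.3.3) with filterByExpr by window, TMM factors and the quasi-likelihood test, and the Benjamini-Hochberg adjusted p had to be under 0.05. The fit tested 14465 genes, with a biological coefficient of variation of 0.153, 6 residual and 5.92 prior degrees of freedom. Windows were compared with PBS and with each other. Variation over time was tested jointly among the 3 IL-2 windows, and as an alternative with a spline of log2 time (3 degrees of freedom). Gene lists of 21 themes were written down beforehand and tested with camera (limma 3.58.1) with a preset correlation of 0.01 or an estimated one. DESeq2 1.42.0 gave the alternative size factors and Wald test. TMM and size factors shifted the median fold change by at most 0.022.

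For classes, log counts of 1500 variable genes were centered within each arm and reduced to 15 principal components (scikit-learn 1.9.0). A graph of 20 neighbors was divided by Leiden clustering at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 1) into 10 clusters. A cluster was named when at least 3 markers and 60% of its marker list exceeded the other cells by a log2 fold of 0.25, and no other list had more genes among its 10 highest. Sums per arm and class with at least 20 cells were fitted with the arm as a block, which left 9 arms and 11040 genes, and the interaction of class and window was tested. Clusters that met no list stayed unnamed and out of the class tests. Cell numbers of clusters were not tested between arms.

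Named genes followed a rule. For each window they were the 10 highest and 10 lowest log2 fold changes among genes past the test, at a mean of at least 20 CPM and on the same side of both PBS arms in every arm of the window. Direct tests between windows and class tests named 8 at each end at the same mean. Single time points named 3 at each end of the log2 ratio to the PBS mean (5 CPM added), among genes of at least 50 CPM in that arm or in both PBS arms. Members of the lists could also be named. Segments of T cell receptors and immunoglobulins (Ighm and Igkc apart), Xist, genes of the Y chromosome, and names starting Gm and a number or ending Rik were tested but not named. Coordinates are those of RefSeq on GRCm38.p6, the assembly called mm10, for the 38999 symbols matched to 1 gene.

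Cells were thinned at random to 3000 UMIs for shares and scores, which left out 1348 cells. A cycling cell had 3 or more UMIs of the G1/S or the G2/M list. Cells with 5 or more UMIs, not thinned, of 28 genes of other cell types (270 cells, 2.03%) were left out in an alternative. These genes were chosen after their levels were seen. Single arms were not tested against each other. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

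The tests were tested on simulated data with a dispersion of 0.02. Every simulated gene had this same dispersion, and no change with time inside a window was simulated. The shares found and the false calls hold for that setting and need not hold for the deposited data. For the middle window against PBS (14094 genes), 75.5% of 98 genes changed 2-fold and 100% of 98 changed 4-fold were found, with 5 false calls. For the difference in middle response between classes (10957 genes), 16.7% of 96 genes changed 2-fold and 70% of 100 changed 4-fold were found, with 5 false calls. For the class difference over all arms (10939 genes) these shares were 95.8% of 96 and 100% of 95, with 14 false calls.

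Alternatives were size factors in place of TMM, DESeq2's Wald test, no filter on low counts, each arm left out in turn, sums thinned to the smallest (595371 UMIs per arm), 86 cells per arm, and sums without cycling cells or without cells of other types. For the classes they were a score of the same markers and a minimum of 50 cells, for shares other minimums (2 and 5 UMIs), percentiles (90 and 99) and no thinning, and for time points each PBS arm alone or 1 CPM added. Each class of the 9 fitted arms held at least 136 cells, so the minimum of 50 cells could change nothing. Chosen after the data were seen were sums without the deposited cluster 1 (1911 cells, median 2785 UMIs), classes from deposited clusters, resting-like sums thinned to the depth of the activated-like ones, and either activated-like cluster alone.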

Results

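The data set holds single-cell RNA counts of regulatory T cells (Tregs) from the spleens of mice whose Foxp3-expressing cells carry GFP. The mice received interleukin-2 (IL-2) bound to the antibody JES6-1, a complex that directs the cytokine to cells with the high-affinity IL-2 receptor, or phosphate-buffered saline (PBS). Cells were taken 1, 2, 4, 8, 16, 24, 64 and 128 h after the complex, and 2 and 128 h after PBS. Each of these 10 arms carried its own hashtag antibody, and all arms were pooled into 1 droplet library. The question addressed was how the time since stimulation shapes gene expression in Tregs. After the authors' filters 13319 cells remained, with a median of 7674 UMIs per cell. The 2 h IL-2 arm held 86 cells and 595371 UMIs. The other arms held 1412 to 1551 cells and 9232399 to 20946655 UMIs. Median UMIs per cell were 5697 and 5871 in the PBS arms at 2 and 128 h. After IL-2 they were 6102.5 at 1 h, 6342 at 2 h, 7140 at 4 h, 8670 at 8 h, 9274 at 16 h, 9698 at 24 h, 13947 at 64 h and 10483 at 128 h.

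Each time point was a single arm, so arms were joined into windows for the tests: early (1, 2 and 4 h), middle (8, 16 and 24 h), late (64 and 128 h) and PBS (2 arms). The windows, tests, gene lists and rules for naming genes were fixed before the data were examined. The labels do not say how many animals an arm holds. P-values therefore measure the spread between arms, which includes the change with time inside a window. The PBS arms differed by more than counting error, with a chi-square of 5.96 per degree of freedom over 13042 genes. A single cell can hold most UMIs of a gene, so this excess need not be a difference between the arms. Values are log2 fold changes of 3 early, 3 middle or 2 late arms against 2 PBS arms, with a standard error. Each standard error is the size of the fold change divided by the square root of the test's F statistic. The spread behind it is estimated over all arms of the fit. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14465 genes, and a call is an adjusted p under 0.05. Every named gene of a window lay on the same side of both PBS arms in each arm of that window, list members aside. Intervals of single arms cover counting error only.

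In the early window, genes downstream of the IL-2 receptor were among those that stood above the PBS arms. The highest fold changes were those of Enah, a regulator of actin filaments (3.15 ± 0.31, adjusted p = 0.000239), and Efna5, a membrane-bound ligand of Eph receptors (2.82 ± 0.41). Hbegf, an EGF family growth factor (2.64 ± 0.20, adjusted p = 0.000153), and the transcription factor gene Myb (2.44 ± 0.24, adjusted p = 0.000239) came next. Dock4 (2.30), the lymphotoxin alpha gene Lta (2.02), Dnah7a (1.99), Gcsh of the glycine cleavage system (1.94), Xbp1, a transcription factor of the unfolded protein response (1.90), and Naf1 (1.89) followed. The lowest were the sialyltransferase gene St8sia6 (-2.06 ± 0.26, adjusted p = 0.00107), Cpm (-1.84), Scml4 (-1.81), Arl5c (-1.79) and Tent5c (-1.70). The IL-7 receptor gene Il7r (-1.69 ± 0.41), Pik3ip1, an inhibitor of PI3 kinase (-1.68), St8sia1 (-1.57), the glucocorticoid-induced gene Tsc22d3 (-1.55) and Slc43a2 (-1.55) completed them. In all, 546 genes were higher and 594 lower in the early arms. Without PBS 2 h these counts were 114 and 119, without PBS 128 h 110 and 154, without 4 h 241 and 201 and without 16 h 358 and 366. Gcsh lost its call without PBS 2 h (1.77) or PBS 128 h (2.13), and Il7r without 2 h (-1.58), 4 h (-1.37) or PBS 2 h (-1.15). Pik3ip1 (-1.46) and Tsc22d3 (-0.94) lost theirs without PBS 2 h, and Enah (1.64), Efna5 (1.61) and Dock4 (2.34) with 86 cells drawn from each arm.

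Known targets of IL-2 and its transcription factor STAT5 rose in 14 of 20 cases and fell in 2 early (16 risen and 2 fallen adjusted over the list alone). As a list they lay above other genes (camera adjusted p = 1.21e-11, but adjusted p = 0.145 with an estimated correlation). None of the 31 calls that camera made over 63 pairs of list and window held with an estimated correlation. The genes that rose included Cish, a feedback inhibitor of cytokine receptors (1.50 ± 0.12, adjusted p = 0.000153), its relatives Socs1 (1.72) and Socs2 (1.53), and the receptor chain gene Il2ra (1.44 ± 0.12, adjusted p = 0.000239). Il2rb (0.90) and Myc, a driver of growth (1.32 ± 0.13, adjusted p = 0.000239), rose as well. Whichever arm was left out, 9 of these calls held, with 10 of 16 calls kept without PBS 128 h. Genes of Treg identity and suppression rose in 9 of 18 cases (12 adjusted over the list alone), with the list above other genes (camera adjusted p = 5.66e-07, but adjusted p = 0.145 with an estimated correlation). Lrrc32, which holds latent TGF-beta at the cell surface (1.65 ± 0.16, adjusted p = 0.000239), and the receptor gene Gpr83 (1.58 ± 0.21) were among the 3 that held whichever arm was left out (3 of 9 calls kept without PBS 2 h and 4 without PBS 128 h). Foxp3 itself rose (0.66 ± 0.16, adjusted p = 0.0282), but its call was lost without 2 h (0.55), 4 h (0.69), 16 h (0.66), PBS 2 h (0.83) or PBS 128 h (0.52). Genes of resting Tregs fell in 5 of 14 cases (1 risen and 7 fallen adjusted over the list alone), and the list lay below other genes (camera adjusted p = 0.000953, but adjusted p = 0.415 with an estimated correlation). The transcription factor genes Tcf7 (-1.51 ± 0.12, adjusted p = 0.000214) and Klf3 (-1.35) and the lymph node homing receptor gene Ccr7 (-0.83) held whichever arm was left out (3 of 5 calls kept without 4 h or PBS 2 h).

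Genes of the nucleolus and of ribosome assembly rose early in 16 of 24 cases (23 adjusted over the list alone), with the list above other genes (camera adjusted p = 7.12e-13, but adjusted p = 0.435 with an estimated correlation). Nop56 (1.26 ± 0.24, adjusted p = 0.00975), Gnl3 (1.27) and Gar1 (1.14) were examples. Of these 16 calls 2 were kept without 4 h, and nearly all were lost without either PBS arm, which leaves a single PBS arm. The mean log2 ratio of the list was 0.46, 0.89 and 1.09 at 1, 2 and 4 h, against -0.0034 and 0.0018 in the PBS arms. Glycolysis and nutrient transport genes rose in 3 of 19 cases, led by the amino acid transporter gene Slc7a5 (1.78), and the glucose transporter gene Slc2a3 fell (-0.97). The count was 5 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.0340, but adjusted p = 0.736 with an estimated correlation), with 0 of 4 calls kept without 4 h, PBS 2 h or PBS 128 h. Of the interferon-stimulated genes Bst2 (0.99), Igtp (0.81) and Isg20 (1.05) rose, 3 of 20 and 3 adjusted over the list alone (camera adjusted p = 0.0150, but adjusted p = 0.773 with an estimated correlation). There were 0 of 3 calls kept without PBS 2 h or PBS 128 h and 1 without 4 h. Chemokine receptor and adhesion genes fell in 6 of 22 cases (7 adjusted over the list alone, camera adjusted p = 0.0111, but adjusted p = 0.527 with an estimated correlation), led by the gut homing receptor gene Ccr9 (-2.55 ± 0.33, adjusted p = 0.00117). Whichever arm was left out 2 held (2 of 6 calls kept without 4 h or PBS 128 h and 3 without PBS 2 h). No nuclear-encoded gene of mitochondrial respiration passed edgeR's test (4 at an unadjusted p under 0.05 and 2 with DESeq2), while the list lay above other genes (camera adjusted p = 0.00577, but adjusted p = 0.773 with an estimated correlation). No ribosomal protein gene passed it (0 at an unadjusted p under 0.05 and 0 with DESeq2), and that list lay below other genes (camera adjusted p = 0.0293, but adjusted p = 0.802 with an estimated correlation).

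In the middle window the highest fold changes were those of Enah (3.71 ± 0.31, adjusted p = 0.000177), Efna5 (3.22), Hbegf (2.81 ± 0.20, adjusted p = 0.000103), Gcsh (2.61 ± 0.34) and Plac8 (2.58 ± 0.32). Hells, a chromatin remodeller of dividing cells (2.36), the replication helicase genes Mcm5 (2.36 ± 0.44, adjusted p = 0.00569) and Mcm3 (2.24), Dnah7a (2.27) and Rmi2 (2.17) followed. The lowest were St8sia6 (-2.52 ± 0.25, adjusted p = 0.000434), the histone deacetylase gene Hdac9 (-2.36 ± 0.36, adjusted p = 0.00272), Il7r (-2.26 ± 0.40), Pgpep1l (-2.12) and Pik3ip1 (-1.83). Klhl24 (-1.68), Card6 (-1.62), Scml4 (-1.59), BE692007 (-1.58) and Tsc22d3 (-1.57) followed. In all, 1623 genes were higher and 1180 lower than in the PBS arms. These counts were 94 and 131 without PBS 2 h, 411 and 390 without PBS 128 h, 798 and 539 without 16 h and 1236 and 718 without 8 h. Without PBS 2 h the calls of Hells (2.18), Mcm5 (2.17), Mcm3 (2.10), Il7r (-1.73), Klhl24 (-1.59), Card6 (-1.41) and Tsc22d3 (-0.97) were lost. That of Mcm3 was also lost without PBS 128 h (2.40). Without cycling cells, those with 3 or more UMIs of the G1/S or G2/M list after thinning to 3000 UMIs, the counts were 968 and 742. The values of Hells (0.70), Mcm5 (0.95) and Rmi2 (1.33) were then lower and Mcm3 (0.53) did not pass, and with 86 cells per arm Mcm5 (1.90) did not.

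Targets of IL-2 and STAT5 rose in 12 of 20 cases and fell in 3 in the middle window (13 risen and 3 fallen adjusted over the list alone, camera adjusted p = 7.49e-07, but adjusted p = 0.233 with an estimated correlation). Cish (1.27 ± 0.11, adjusted p = 0.000249), Socs2 (1.91) and Il2rb (1.20) rose, and the transcriptional repressor gene Bcl6 fell (-1.41 ± 0.24, adjusted p = 0.00426). Whichever arm was left out, 9 of the 15 calls held (9 of 15 calls kept without PBS 2 h). Treg identity genes rose in 9 of 18 cases and Nrp1 fell (-0.73), with 10 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000187, but adjusted p = 0.233 with an estimated correlation). Gpr83 (1.40 ± 0.21), Capg (1.38) and the co-stimulatory receptor gene Tnfrsf18 (0.94) were among the 5 that held whichever arm was left out (6 of 10 calls kept without PBS 2 h). Foxp3 stood at -0.09 ± 0.15, adjusted p = 0.726. Resting Treg genes fell in 8 of 14 cases and Igfbp4 rose (0.79), with 1 risen and 10 fallen adjusted over the list alone (camera adjusted p = 9.16e-06, but adjusted p = 0.233 with an estimated correlation). Tcf7 (-1.44 ± 0.12, adjusted p = 0.000177), Klf3 (-1.15) and S1pr1, a receptor for exit from lymphoid organs (-1.06), held whichever arm was left out (3 of 9 calls kept without PBS 2 h). Interferon-stimulated genes rose in 9 of 20 cases and Ly6c1 fell (-0.93), with 11 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000174, but adjusted p = 0.620 with an estimated correlation). Isg20 (1.75 ± 0.24, adjusted p = 0.00212) and Igtp (1.06) held whichever arm was left out (2 of 10 calls kept without PBS 2 h or PBS 128 h and 6 without 16 h).

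Genes of DNA replication at the G1/S transition rose in 17 of 25 cases in the middle window (21 adjusted over the list alone, camera adjusted p = 3.89e-09, but adjusted p = 0.527 with an estimated correlation). Early, 0 of 25 had passed edgeR's test (0 at an unadjusted p under 0.05 and 0 with DESeq2). Mcm6 (1.52), Pcna (1.17) and Cdt1 (1.20) rose, with 0 of 17 calls kept without PBS 2 h, 4 without PBS 128 h and 11 without 16 h or 24 h. Nuclear-encoded genes of mitochondrial respiration rose in 19 of 22 cases (20 adjusted over the list alone, camera adjusted p = 1.37e-09, but adjusted p = 0.435 with an estimated correlation). Cycs (1.15), Cox5a (0.91 ± 0.16, adjusted p = 0.00497) and Uqcrq (0.94) were examples, with 0 of 19 calls kept without PBS 2 h and 8 without PBS 128 h. Nucleolar genes rose in 18 of 24 cases (22 adjusted over the list alone, camera adjusted p = 3.89e-09, but adjusted p = 0.527 with an estimated correlation), for example Gar1 (1.21) and Ncl (0.94). There were 0 of 18 calls kept without PBS 2 h or PBS 128 h, 8 without 8 h and 9 without 16 h. Glycolysis genes rose in 10 of 19 cases and Slc2a3 fell (-0.95), with 12 risen and 1 fallen adjusted over the list alone (camera adjusted p = 2.96e-05, but adjusted p = 0.435 with an estimated correlation). Gapdh (1.07) and Eno1 (1.34) were examples, with 0 of 11 calls kept without PBS 2 h and 6 without PBS 128 h. Of the cholesterol synthesis genes Fdps (1.11), Idi1 (0.85) and Mvd (1.24) rose, 3 of 19 and 2 adjusted over the list alone (camera adjusted p = 0.00541, but adjusted p = 0.736 with an estimated correlation), with 0 of 3 calls kept without PBS 2 h and 1 without PBS 128 h. Early, Mvd alone had risen (0.73, 0 adjusted over the list alone), with the call lost without 4 h, 8 h, 16 h, 24 h, PBS 2 h or PBS 128 h.

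**Figure D1:**
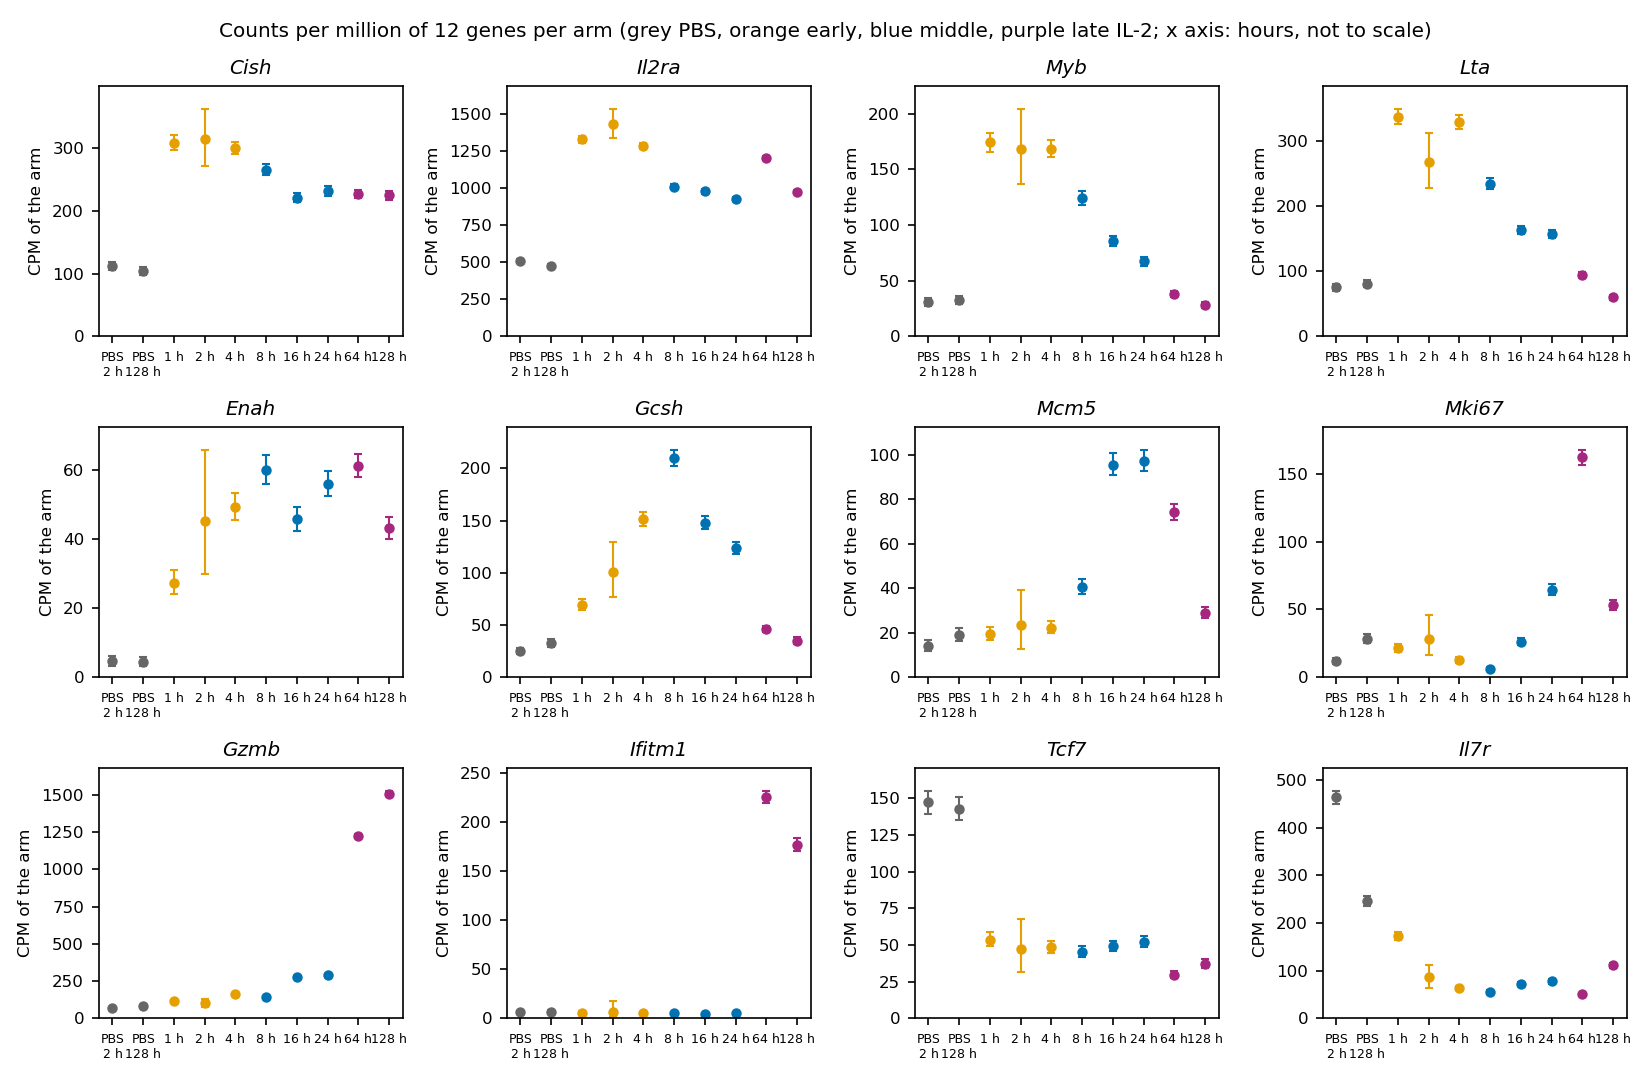
Expression of 12 genes per arm in CPM, UMIs scaled to a common total (vertical axes), in order of time after PBS (grey) or IL-2 complex (orange early, blue middle, purple late), with exact 95% Poisson intervals as bars and time not drawn to scale. Cish stood at 112 and 104 CPM in the PBS arms and 309 CPM at 1 h, and Gzmb reached 1509 CPM at 128 h.

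In the late window the interferon-induced transmembrane genes Ifitm1 (5.07 ± 0.17, adjusted p = 2.65e-08; GRCm38.p6 chromosome 7, 140967429 to 140969827), Ifitm2 (4.35 ± 0.36, adjusted p = 3.46e-05) and Ifitm3 (4.03 ± 0.44, adjusted p = 0.000181) had high fold changes. They are similar paralogs on 1 chromosome, so how reads were shared between them is uncertain. The granzyme genes Gzma (4.34 ± 0.59, adjusted p = 0.000639) and Gzmb, a protease of cytotoxic granules (4.22 ± 0.34, adjusted p = 3.39e-05; chromosome 14, 56258836 to 56262334), were also among the highest. Lgals7 (3.95), Enah (3.59), Plac8 (3.29), Dnah7a (3.11) and the kinetochore gene Spc24 (3.07 ± 0.79) followed. A UMI of Gzma was found in 9.75% of thinned cells at 64 h and 4.81% at 128 h. In the PBS arms the shares were 1.60% and 2.05%. The fold change of Gzma thus rests on a minority of cells. For Gzmb the shares were 51.8% and 59.8%, against 16.5% and 18.0%. The lowest were St8sia6 (-4.28 ± 0.31, adjusted p = 1.53e-05), Hdac9 (-3.79), the activation marker Cd83 (-3.37 ± 0.28, adjusted p = 3.39e-05), Il7r (-2.10) and Igf1r (-2.08). Itm2a (-2.07), Tcf7 (-2.07 ± 0.13, adjusted p = 8.05e-06), Ttc28 (-2.04), St8sia1 (-2.02) and Atp1b1 (-1.99) followed. In all, 1816 genes were higher and 1398 lower than in the PBS arms. Without 64 h these counts were 761 and 433, without PBS 2 h 501 and 427 and without PBS 128 h 955 and 724. The call of Spc24 was lost in each case (1.61, 2.81 and 3.41), without cycling cells (0.70) and with 86 cells per arm (3.23). That of Il7r was lost without 64 h (-1.66) or PBS 2 h (-1.55), and those of Itm2a (-1.73) and St8sia1 (-1.39) with every arm thinned to the smallest. With 86 cells per arm Hdac9 stood at -2.42, smaller but past the test. Cells with 5 or more UMIs of 28 genes of other cell types made up 4.86% of the 64 h arm and 3.49% of the 128 h arm, against 1.04% and 0.795% of the PBS arms. Cells were not thinned for this share, so it rises with depth by construction. Without them 1851 genes were higher and 1378 lower.

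Genes of activated Tregs rose in 14 of 26 cases late and fell in 3 (17 risen and 5 fallen adjusted over the list alone, camera adjusted p = 0.000187, but adjusted p = 0.527 with an estimated correlation), and 11 of the 17 calls held whichever arm was left out. Arm sums mix classes of cells that are described below. Activated-like cells made up 8.85% and 10.7% of the PBS arms, but 18.8% at 64 h and 24.2% at 128 h. Resting-like cells made up 52.0% and 48.9%, against 30.2% and 39.2%. How far these shares account for the late values was not tested. S100a6 (2.62 ± 0.37, adjusted p = 0.000824), the galectin gene Lgals1 (2.20 ± 0.30, adjusted p = 0.000605) and the co-stimulatory receptor genes Icos (1.25 ± 0.11, adjusted p = 3.95e-05) and Tnfrsf9 (1.25) rose. So did the IL-33 receptor gene Il1rl1 (2.08), and Rorc, which encodes a transcription factor of IL-17-producing cells, fell (-2.72 ± 0.37, adjusted p = 0.000627). Of the same list 2 rose and 2 fell early (3 risen and 3 fallen adjusted over the list alone), and 5 of 26 rose and 2 fell in the middle window (5 risen and 2 fallen adjusted over the list alone). There were 0 of 4 calls kept without PBS 128 h, 1 without 16 h or PBS 2 h and 2 without 1 h, 8 h or 24 h early, and 1 of 7 calls kept without PBS 2 h, 3 without PBS 128 h and 4 without 16 h or 24 h in the middle window. Treg identity genes rose late in 11 of 18 cases and Nrp1 fell (-0.77), with 11 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000225, but adjusted p = 0.233 with an estimated correlation). Tnfrsf18 (1.18 ± 0.13, adjusted p = 0.000188), Ctla4 (0.87 ± 0.13) and the ectonucleotidase gene Entpd1 (1.17) were among the 7 of 12 that held whichever arm was left out, and Foxp3 stood at -0.23 ± 0.17, adjusted p = 0.355. Resting Treg genes fell in 9 of 14 cases and Igfbp4 rose (1.05), with 1 risen and 9 fallen adjusted over the list alone (camera adjusted p = 1.52e-05, but adjusted p = 0.233 with an estimated correlation). Ccr7 (-1.28 ± 0.13), Bach2 (-0.93) and Satb1 (-0.91) were among the 7 of 10 that held whichever arm was left out. IL-2 and STAT5 targets rose in 11 of 20 cases and fell in 2 (11 risen and 2 fallen adjusted over the list alone, camera adjusted p = 7.14e-05, but adjusted p = 0.233 with an estimated correlation). Socs2 (2.38 ± 0.18, adjusted p = 1.65e-05), Cish (1.12) and Il2ra (1.20) were among the 9 of 13 that held whichever arm was left out, and Myc stood at 0.11 ± 0.13, adjusted p = 0.575.

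Genes of mitosis (G2/M) rose late in 19 of 24 cases (24 adjusted over the list alone, camera adjusted p = 6.72e-07, but adjusted p = 0.607 with an estimated correlation), but in 8 with DESeq2. Early, 0 of 24 passed edgeR's test (0 at an unadjusted p under 0.05 and 0 with DESeq2), and in the middle window 0 did (1 at an unadjusted p under 0.05 and 0 with DESeq2). Mki67, a marker of proliferation (2.49 ± 0.80, adjusted p = 0.0449), Top2a (2.88 ± 0.81, adjusted p = 0.0252) and Birc5 (2.75) rose late, with 0 of 19 calls kept without 64 h, PBS 2 h or PBS 128 h, 6 without 2 h and 9 without 16 h. G1/S genes rose in 15 of 25 cases (24 adjusted over the list alone, camera adjusted p = 1.05e-06, but adjusted p = 0.607 with an estimated correlation), with 0 of 15 calls kept without 64 h or PBS 2 h, 1 without PBS 128 h and 9 without 2 h. The mean log2 ratios at 64 and 128 h were 2.33 and 0.79 for G2/M and 1.53 and 0.47 for G1/S genes. Without cycling cells 2 of the 19 mitotic calls and 1 of the 15 G1/S calls were kept. Cholesterol synthesis genes rose in 11 of 19 cases (15 adjusted over the list alone, camera adjusted p = 6.32e-06, but adjusted p = 0.527 with an estimated correlation). Of these Mvd (1.69 ± 0.20, adjusted p = 0.000278) held whichever arm was left out, with 1 of 11 calls kept without 64 h or PBS 2 h and 6 without PBS 128 h. Glycolysis genes rose in 11 of 19 cases (14 adjusted over the list alone, camera adjusted p = 2.81e-06, but adjusted p = 0.415 with an estimated correlation). Gapdh (1.10 ± 0.19, adjusted p = 0.00233) and the transferrin receptor gene Tfrc (1.82 ± 0.24) were among the 4 that held whichever arm was left out (5 of 11 calls kept without 64 h or PBS 2 h). Respiration genes rose in 14 of 22 cases and Sdha fell (-0.40), with 16 risen and 1 fallen adjusted over the list alone (camera adjusted p = 3.33e-06, but adjusted p = 0.527 with an estimated correlation), with 1 of 15 calls kept without PBS 2 h, 2 without 64 h, 4 without PBS 128 h and 9 without 16 h. No nucleolar gene passed edgeR's test late (0 at an unadjusted p under 0.05 and 0 with DESeq2).

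Ribosomal protein genes fell late in 10 of 22 cases (11 adjusted over the list alone, camera adjusted p = 8.56e-06, but adjusted p = 0.602 with an estimated correlation). All fold changes are relative to the total RNA counted in an arm. Median UMIs per cell were 2.41 and 1.81 times those of the PBS arms at 64 and 128 h. A late fall of these or of mitochondrially encoded genes therefore need not mean fewer UMIs per cell. Rps27 (-0.77) and Rps24 (-0.74) held whichever arm was left out (2 of 10 calls kept without PBS 2 h, 3 without 64 h, 4 without PBS 128 h and 6 without 128 h). Rps12 (0.71) and Rps2 (0.67) rose in the middle window (2 adjusted over the list alone), with 0 of 2 calls kept without PBS 2 h or PBS 128 h. Mitochondrially encoded genes fell late in 6 of 10 cases (9 adjusted over the list alone, camera adjusted p = 1.21e-05, but adjusted p = 0.415 with an estimated correlation). Of these mt-Nd2 (-0.76) and mt-Nd5 (-0.68) held whichever arm was left out (2 of 6 calls kept without 64 h and 3 without PBS 2 h or PBS 128 h). The early count was 0 (0 at an unadjusted p under 0.05 and 0 with DESeq2), and in the middle window mt-Co1 fell (-0.59, 1 adjusted over the list alone), with the call lost without PBS 2 h. Of the interferon-stimulated genes 6 of 20 rose late and Ly6c1 fell (-1.10), with 8 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.00136, but adjusted p = 0.736 with an estimated correlation), and 4 of 7 held whichever arm was left out. The mean log2 ratio of the list was 0.97 at 64 h but 0.15 at 128 h, against 0.11 and -0.13 in the PBS arms. Chemokine receptor and adhesion genes rose late in 7 of 22 cases and fell in 6 (8 risen and 8 fallen adjusted over the list alone), among them Ccr5 (2.54 ± 0.28, adjusted p = 0.000188) and Ccr6 (-2.38 ± 0.38). The list had a late median of 0.11 and a mean of -0.04, with 4 of 13 calls kept without PBS 2 h and 8 without 64 h. Of the same genes 5 of 22 fell in the middle window (5 adjusted over the list alone, camera adjusted p = 0.0220, but adjusted p = 0.527 with an estimated correlation), with Ccr9 at -2.02, with 3 of 5 calls kept without 16 h or PBS 2 h.

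**Figure D2:**
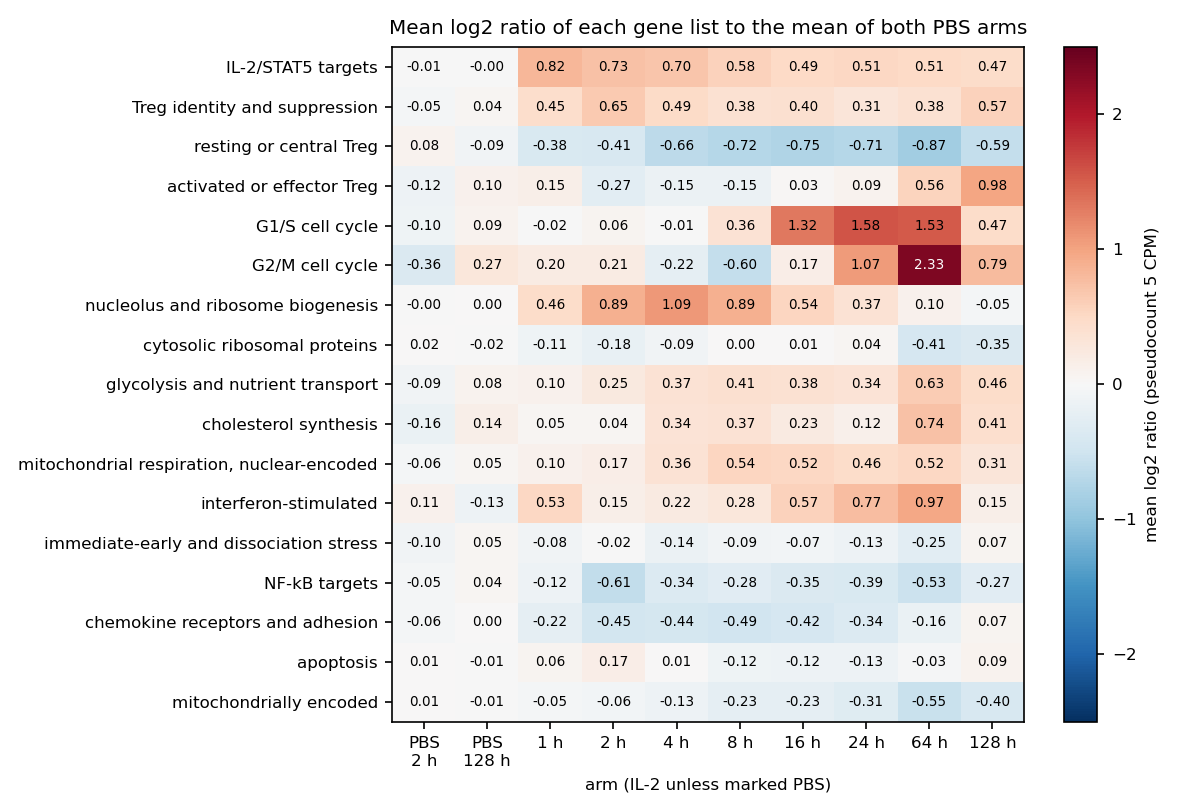
Mean log2 ratio of each of 17 gene lists (vertical axis) in each of 10 arms (horizontal axis) to the mean of the PBS arms, with 5 CPM added to all values and color giving the ratio. IL-2 and STAT5 targets stood at 0.82 at 1 h, nucleolar genes at 1.09 at 4 h, G1/S genes at 1.58 at 24 h and G2/M genes at 2.33 at 64 h.

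Immediate-early genes, which tissue dissociation can also induce, gave mixed counts. Early, Dusp1 (0.64) and Jund (0.76) rose and Btg2 fell (-1.12), 3 of 16 (3 risen and 3 fallen adjusted over the list alone), with 0 of 3 calls kept without PBS 2 h and 1 without PBS 128 h. In the middle window Dusp1 (0.54) and the near-identical heat shock genes Hspa1a (2.56) and Hspa1b (2.59), whose reads cannot be separated with certainty, rose. Btg2 (-0.96), Egr1 (-0.99) and Zfp36 (-0.80) fell (3 risen and 3 fallen adjusted over the list alone), the list's median being -0.02 and its mean 0.11, with 0 of 6 calls kept without PBS 2 h and 3 without 16 h or PBS 128 h. Late, Fos rose (1.75) and Btg2 fell (-0.79, 1 risen and 1 fallen adjusted over the list alone), with 0 of 2 calls kept without PBS 2 h and 1 without 64 h or PBS 128 h. Of 13 NF-kB targets Cd83 (-0.87), Tnfaip3 (-1.61) and Tnip1 (-0.62) fell early and Bcl3 rose (0.67, 1 risen and 3 fallen adjusted over the list alone), with 0 of 4 calls kept without PBS 2 h, 1 without 4 h or PBS 128 h and 2 without 1 h. Of these targets 3 fell in the middle window (4 adjusted over the list alone), with 0 of 3 calls kept without PBS 2 h or PBS 128 h and 1 without 16 h. Late, 4 fell and Bcl3 rose (1 risen and 5 fallen adjusted over the list alone), and Cd83 held whichever arm was left out (1 of 5 calls kept without 64 h or PBS 2 h and 2 without PBS 128 h). Of 16 apoptosis genes 4 rose and 2 fell early (6 risen and 3 fallen adjusted over the list alone), with Casp8 at 1.16 ± 0.15, adjusted p = 0.00120 and the p53-inducible gene Bbc3 at -1.58, with 2 of 6 calls kept without PBS 128 h and 3 without PBS 2 h. Of the same list 3 rose and 3 fell in the middle window (3 risen and 3 fallen adjusted over the list alone, median 0.11, mean -0.04), with 1 of 6 calls kept without PBS 2 h and 2 without PBS 128 h. Late, 3 rose, led by the executioner caspase gene Casp3 (1.68 ± 0.20, adjusted p = 0.000274), and 2 fell (3 risen and 2 fallen adjusted over the list alone, median -0.02, mean 0.08), with 3 of 5 calls kept without 64 h, PBS 2 h or PBS 128 h.

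Markers of other cell types were tested as lists too. Of 6 B cell markers 0 passed edgeR's test early (3 at an unadjusted p under 0.05 and 1 with DESeq2, 1 risen and 2 fallen adjusted over the list alone, median -0.41, mean 0.03) and 0 in the middle window (1 at an unadjusted p under 0.05 and 0 with DESeq2). Late, Cd79b (0.71) and Ighm (0.56) rose and Ly6d fell (-2.72, 2 risen and 1 fallen adjusted over the list alone), with 0 of 3 calls kept without PBS 2 h and 1 without 64 h. Of 6 markers of CD8 T and natural killer cells 0 passed early (1 at an unadjusted p under 0.05 and 0 with DESeq2, 1 adjusted over the list alone) and 0 in the middle window (2 at an unadjusted p under 0.05 and 0 with DESeq2). Late, Gzma and Nkg7 (2.33) rose and Eomes fell (-2.52, 2 risen and 1 fallen adjusted over the list alone), and the call of Nkg7 was lost without PBS 2 h. Without the cells that held 5 or more UMIs of the 28 genes of other types, Cd79b (one of the 28) stood at 0.51, Ighm at 0.53, Gzma at 4.34 and Nkg7 at 2.33, each past the test. Of 8 myeloid markers 0 passed early (1 at an unadjusted p under 0.05 and 0 with DESeq2), Cst3 rose in the middle window (0.31, 0 adjusted over the list alone), and Tyrobp fell late (-1.43, 1 risen and 2 fallen adjusted over the list alone). The call of Cst3 was lost without 8 h, 16 h, 24 h, 128 h, PBS 2 h or PBS 128 h, and that of Tyrobp without 64 h or PBS 128 h. Of 5 erythroid and platelet markers 0 passed in any window (early 1 at an unadjusted p under 0.05 and 0 with DESeq2; middle 0 at an unadjusted p under 0.05 and 0 with DESeq2; late 2 at an unadjusted p under 0.05 and 0 with DESeq2).

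In the direct test of the middle against the early arms, genes of DNA replication were among those with the highest differences. Mcm3 (2.20 ± 0.44, adjusted p = 0.0458), the Notch regulator Dtx1 (2.13 ± 0.29, adjusted p = 0.0243), Hells (2.02), Mcm5 (1.98) and Plac8 (1.79 ± 0.28) stood at the top. The chromatin assembly gene Chaf1b (1.58), Drc1 (1.55) and Mcm6 (1.46) followed. Tent5a (-1.36 ± 0.19, adjusted p = 0.0243), the protease gene Adam19 (-1.20), Klf6 (-0.95), P2ry10 (-0.89) and Spred1, an inhibitor of Ras signaling (-0.89), had the lowest. Fnip1 (-0.86), Clint1 (-0.84) and Rgs1, a regulator of G protein signaling (-0.80), followed. By the direct test 104 genes were higher and 55 lower in the middle arms. Without the 1 h, 2 h, 16 h or 24 h arm edgeR gave 0 genes, so all of these calls were lost. At an unadjusted p under 0.05 there were then 1375, 1432, 1167 and 1144 higher and 859, 1054, 631 and 789 lower genes. The counts were 7 and 10 without either PBS arm, 484 and 208 without 4 h, 340 and 125 without 8 h, 381 and 159 without 64 h and 344 and 143 without 128 h. DESeq2's Wald test gave 517 and 270. Without cycling cells Mcm3 (0.70), Hells (0.62), Mcm5 (0.56), Chaf1b (0.62) and Mcm6 (0.38) did not pass. With every arm thinned to the smallest Chaf1b (1.39) and Fnip1 (-0.73) did not. With 86 cells per arm 8 of the 16 did not: Mcm5 (1.91), Plac8 (1.17), Chaf1b (0.98), Drc1 (1.65), Tent5a (-1.58), P2ry10 (-0.96), Spred1 (-1.01) and Fnip1 (-0.62).

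From the middle to the late window, 633 genes rose and 523 fell. Ifitm1 (5.29 ± 0.15, adjusted p = 2.00e-09), Gzma (4.11 ± 0.48, adjusted p = 0.000800), Ifitm2 (3.08), Lgals7 (2.66) and Gzmb (2.46 ± 0.27, adjusted p = 0.000576) rose the most. Nckap5 (2.43), Frmd5 (2.39, 1.58 without 128 h) and Ifitm3 (2.33, 1.55 without 64 h) followed. Cd83 (-2.40 ± 0.26, adjusted p = 0.000513), Gcsh (-2.05), St8sia6 (-1.77) and the tRNA methyltransferase gene Mettl1 (-1.72 ± 0.39) fell the most. Rragd, a regulator of mTORC1 (-1.58), Gpr83 (-1.55 ± 0.21, adjusted p = 0.00167), Myb (-1.54 ± 0.23, adjusted p = 0.00242) and Smyd2 (-1.41) followed. St8sia6 (-0.78), Rragd (-1.09) and Smyd2 (-1.35) did not pass with every arm thinned to the smallest, Frmd5 (2.01) and Smyd2 (-1.42) did not with 86 cells per arm, and Mettl1 did not without 64 h (-1.75) or 128 h (-1.68). With 86 cells per arm St8sia6 stood at -3.20 and passed. The counts were 215 and 142 without 16 h, 287 and 240 without 8 h, 444 and 262 without 64 h and 358 and 186 without 128 h. A joint test of any difference among the 3 IL-2 windows found 2572 genes, 1360 without 16 h and 1660 without 64 h. A spline of log2 time over the 8 IL-2 arms found 3943 genes, of which 2216 were found by both.

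At single time points there was no replicate, and values are log2 ratios of an arm to the mean of the PBS arms with 5 CPM added. The highest ratios were those of Myb (2.30), Xbp1 (2.06) and Lta (2.05) at 1 h, and Dock4 (2.35), Myb (2.25) and Epcam (2.19) at 2 h. They were those of Efna5 (2.57), Myb (2.25) and Gcsh (2.21) at 4 h, and Efna5 (2.89), Enah (2.78) and Gcsh (2.67) at 8 h. At 16 h they were Efna5 (2.32), Mcm5 (2.22) and Mcm3 (2.22), and at 24 h the transglutaminase gene Tgm2 (3.02), Enah (2.68) and Plac8 (2.67). Ifitm2 (4.45), Ifitm1 (4.36) and Ifitm3 (4.35) were highest at 64 h, and Gzmb (4.22), Ifitm1 (4.02) and Ifitm2 (3.57) at 128 h. The lowest were Slc35d1 (-1.60), Pou2f2 (-1.48) and Dtx1 (-1.47) at 1 h and Arl5c (-2.12), Cpm (-2.04) and Il7r (-1.99) at 2 h. From 4 to 64 h they were Il7r, St8sia6 and Hdac9, at -2.40, -2.22 and -2.06 at 4 h and -2.69, -3.25 and -3.09 at 64 h. At 128 h they were Hdac9 (-3.23), St8sia6 (-3.22) and Tcf7 (-1.84). Between the PBS arms, 2 h over 128 h, the log2 ratio was 0.90 for Il7r, 0.41 for Efna5 and -0.58 for Hdac9. Over 3422 genes the median size of the ratio was 0.0980 between the PBS arms, 0.161 at 1 h, 0.314 at 8 h, 0.359 at 64 h and 0.230 at 128 h. Cish stood at 112 CPM (95% interval 105 to 119) in the PBS 2 h arm, 309 (297 to 320.1) at 1 h and 225 (218 to 232) at 128 h. Mki67 stood at 12.1 CPM (9.95 to 14.5), 162 at 64 h (157 to 168) and 53.0 at 128 h (49.5 to 56.7).

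Per cell, the share with 3 or more UMIs of the 24 G2/M genes was counted after thinning to 3000 UMIs. It was 2.43% (exact 95% interval 1.67 to 3.42) and 2.50% (1.73 to 3.49) in the PBS arms. After IL-2 it was 2.56% at 1 h, 1.52% at 4 h, 1.75% at 8 h, 3.82% at 16 h and 8.94% (7.44 to 10.6) at 24 h. It reached 30.0% (27.5 to 32.5) at 64 h and was 7.94% (6.57 to 9.50) at 128 h. The 2 h arm had 3 of 74 such cells, 4.05% (0.844 to 11.4). Unthinned, the share was 8.40% and 10.5% in the PBS arms and 55.5% at 64 h. The share with 3 or more UMIs of the G1/S genes was 13.1% and 16.9% in the PBS arms, 15.9% at 1 h, 13.5% at 4 h, 22.1% at 8 h, 35.3% at 16 h, 37.2% at 24 h, 34.9% at 64 h and 17.6% at 128 h. Free RNA of the pooled library was not measured, and the PBS arms held cycling-like cells too, so the PBS share is no measure of background alone.

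The score of the IL-2 and STAT5 targets was the sum of their UMIs per 3000 UMIs of a cell. It shows how far the cells of an arm shifted, and evenness of the response was not tested. It also counts Bcl6 and Ccnd3, which fell in every window. Its median was 12 and 11 in the PBS arms, 22 at 1 h, 25 at 2 h, 21 at 4 h, 19 at 8 h, 18 at 16 h, 19 at 24 h, 20 at 64 h and 19 at 128 h. The 10th percentile was 5 in both PBS arms, 13 at 1 h and 4 h, and 10 or 11 from 8 h on. The 95th percentile of the PBS cells, 26, was passed by 5.70% and 3.18% of the cells of the PBS arms. It was passed by 30.5% (27.9 to 33.1) at 1 h, 39.2% (28.0 to 51.2) at 2 h and 26.0% (23.8 to 28.4) at 4 h. From 8 h on the shares were 15.8%, 17.4% at 16 h, 19.6% at 24 h, 21.1% at 64 h and 18.8% at 128 h. In resting-like cells, a class of clusters, the median was 14 and 13 in the PBS arms and 25 at 1 h. In activated-like cells it was 9 in both PBS arms, 17 at 1 h and 21 at 4 h. At 1 h 31.6% of the resting-like and 43.8% of the activated-like cells passed the PBS percentile of their own class (29 and 19).

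**Figure D3:**
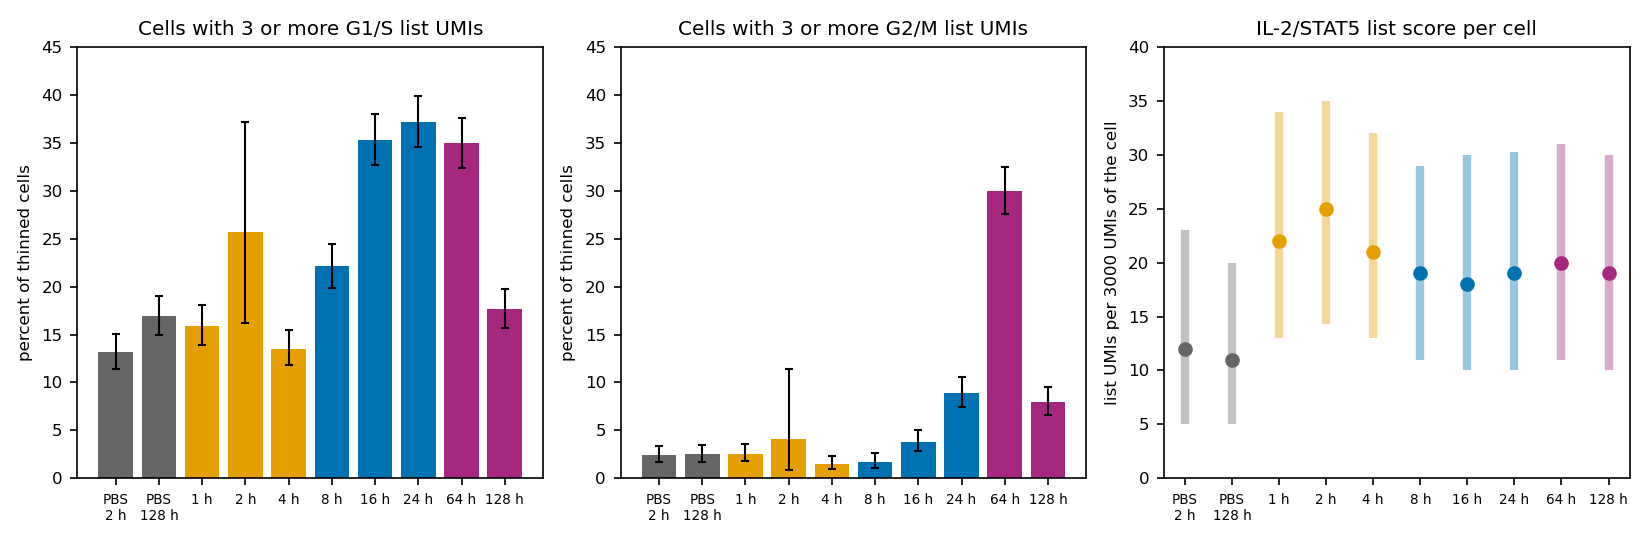
Share of cells with 3 or more UMIs of the G1/S or of the G2/M genes after thinning to 3000 UMIs (percent, exact 95% binomial intervals) and score of the IL-2 and STAT5 targets (list UMIs per 3000 UMIs, median with the 10th to 90th percentile as bar) in each of the 10 arms. The G2/M share was 30.0% at 64 h against 2.43% and 2.50% in the PBS arms, and the score had a median of 22 at 1 h against 12 and 11.

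The deposited clusters carry no names, so cells were clustered again after centering each arm, and clusters were named from markers fixed beforehand. Clusters 2, 3 and 4 were resting-like and clusters 6 and 7 activated-like. The classes were compared over the 9 arms with 20 or more cells in both (the 2 h arm had 17 activated-like cells). Klrg1 (5.34), a receptor of terminally differentiated lymphocytes, the leukotriene receptor gene Ltb4r1 (5.31), Arnt2 (5.09) and Ccr2 (4.97) were the highest in activated-like cells. S100a4 (4.91), Lgals3 (4.88), Tmem37 (4.76) and Frmd5 (4.45) followed. Efna5 (-4.11), Bach2 (-3.67), Igfbp4 (-3.62) and Fgf13 (-3.14) were the lowest, before Tnfsf8 (-3.05), Dock4 (-2.89), Nsg2 (-2.77) and Ccr7 (-2.69). Of 11040 genes 6772 differed, 3411 higher and 3361 lower in activated-like cells. This describes the classes and is no independent finding, since expression defined them. Classes from a score of the same markers gave smaller differences for the 8 lowest, all past the test: Efna5 (-1.35), Bach2 (-1.90), Igfbp4 (-2.14), Fgf13 (-1.34), Tnfsf8 (-1.11), Dock4 (-1.51), Nsg2 (-1.05) and Ccr7 (-1.31). So did classes from deposited clusters for Bach2 (-2.09), Fgf13 (-1.21), Tnfsf8 (-1.04), Dock4 (-1.58), Nsg2 (-1.23) and Ccr7 (-1.38). Unnamed clusters held 383 to 577 cells per arm (27 in the 2 h arm), and interferon-like cells 13 to 67 (4 in the 2 h arm). Cycling-like cells numbered 4 and 10 in the PBS arms, 11 at 1 h, 1 at 2 h, 9 at 4 h, 15 at 8 h, 105 at 16 h, 164 at 24 h, 274 at 64 h and 68 at 128 h.

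The response to IL-2 was compared between both classes by the interaction of class and window. The difference is the log2 change against PBS in activated-like cells minus that in resting-like cells. A positive difference can thus be a larger rise or a smaller fall in activated-like cells, and a negative one a smaller rise or a larger fall. Cluster 6 held 76 and cluster 7 60 cells of the PBS 2 h arm but 162 and 198 of the 128 h arm, so the mix of the activated-like class was not the same in these arms (not tested). Expression of the same cells defined the classes. Among the 10 genes of highest fold were Gzmb, Tmem37 and Ifitm1 in cluster 7 and Cd200r1 in cluster 6. Efna5, Cd55 and Satb1 were so in cluster 3, and Igfbp4, Ly6c1, Plac8 and Ecm1 in cluster 4. For such genes a difference in response can come from how cells were sorted, and its p-value does not account for this. In the early window 52 genes differed, 39 positive and 13 negative. Gzmb (1.65 ± 0.25, adjusted p = 0.000935), Slc35d1 (1.64), Rarg (1.60), Scml4 (1.59), Pecam1 (1.46), Cd200r1 (1.40), Itgb8 (1.38) and Etfbkmt (1.37) had the highest differences. Efna5 (-3.59 ± 0.85), the kinase gene Sgk1 (-2.71 ± 0.37, adjusted p = 0.000431), Prickle1 (-2.01), Lpar6 (-1.71), Cd55 (-1.28), Ecm1 (-1.22), Mcub (-1.20) and Wwp1 (-1.15) had the lowest. Sgk1, the one of the 16 whose call held whichever arm was left out, responded by -0.76 in activated-like and 1.93 in resting-like cells. With classes from a score its difference was -1.11 and did not pass, and 3 of the 16 calls were kept, against 10 with classes from deposited clusters, 11 with cluster 6 alone and 6 with cluster 7 alone. Gzmb stood at 0.98 without 4 h and Efna5 at -0.74 without PBS 128 h, both no longer past the test. Gzmb also lost its call without PBS 2 h (1.36), with DESeq2 (1.61) and with cluster 6 alone (1.11). The count was 25 without 1 h, 20 without 4 h, 16 without PBS 2 h, 6 without PBS 128 h and 15 with classes from a score. With every sum thinned to the smallest edgeR gave 0 of the 1713 genes then tested, with 54 higher and 50 lower at an unadjusted p under 0.05. DESeq2 gave 31 on full sums.

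In the middle window 52 genes differed between the classes, 31 positive and 21 negative. Gzmb responded by 2.48 in activated-like and 0.34 in resting-like cells (2.14 ± 0.23, adjusted p = 2.14e-06). Iigp1, an interferon-inducible GTPase gene, responded by -0.27 and 1.64 (-1.86 ± 0.20, adjusted p = 2.14e-06). Both held whichever arm was left out. Tmem37 (3.29), Cdkn2c (1.55), Rcan3 (1.55), Tuba1c (1.41), Slc35d1 (1.32), Epcam (1.31) and Cd200r1 (1.22) were the other highest. Efna5 (-4.38, -1.53 without PBS 128 h), Lpar6 (-1.77), Sgk1 (-1.64), Myo1f (-1.58), Cd83 (-1.50), Ecm1 (-1.35) and Acot7 (-1.16) were the other lowest. These 14 each lost the call without a PBS arm, and the count was 7 without either PBS arm and 33 without 16 h. With classes from a score 4 of the 16 calls were kept, with classes from deposited clusters 6 were, and with clusters 6 and 7 alone 14 and 7 were. With deposited clusters Slc35d1 stood at -0.14 and Myo1f at 0.000603, and Iigp1 fell to -0.88 (-0.96 from a score). With cluster 7 alone Iigp1 did not pass (-1.26).

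In the late window 304 genes differed, 127 positive and 177 negative. Ifitm1 responded by 6.49 in activated-like and 2.98 in resting-like cells (3.49 ± 0.52, adjusted p = 0.000203), and the lipid-binding protein gene Fabp5 by 2.80 and 0.67 (2.14 ± 0.23, adjusted p = 8.98e-07). Satb1 responded by 1.56 and -0.82 (2.37 ± 0.19, adjusted p = 6.98e-09), and Cd83 by -5.13 and -2.11 (-3.09 ± 0.44, adjusted p = 0.000125). Sorcs2 (2.26), Tmem37 (2.24), Ly6c1 (1.73), Slc35d1 (1.66) and Alcam (1.63) were the other highest. Myo1f (-2.74), Igfbp4 (-2.73), Rap1gap2 (-2.72), Plac8 (-2.68), Ccr6 (-2.29), Il1rl1 (-2.21) and Mir155hg (-2.10) were the other lowest. Fabp5, Satb1, Slc35d1, Cd83, Myo1f and Rap1gap2 held whichever arm was left out. Without PBS 128 h the calls of Ifitm1 (2.60), Sorcs2 (1.68), Tmem37 (1.20), Alcam (0.83), Igfbp4 (-3.17), Plac8 (-2.61) and Mir155hg (-1.85) were lost. Without PBS 2 h those of Ly6c1 (1.14), Igfbp4 (-2.18), Plac8 (-2.70), Ccr6 (-1.84), Il1rl1 (-2.05) and Mir155hg (-2.26) were lost. Without 64 h Tmem37 (1.81), Alcam (1.43) and Mir155hg (-2.11), and without 128 h Igfbp4 (-2.27), Ccr6 (-1.92) and Mir155hg (-2.09), did not pass. The count was 46 without PBS 2 h, 108 without PBS 128 h, 184 without 64 h and 196 without 128 h. It was 121 with DESeq2, 601 with classes from a score and 6 with every sum thinned to the smallest, where 1713 genes were tested. With classes from deposited clusters Slc35d1 (-0.39) and Ccr6 (0.97) changed sign, Satb1 stood at 0.79 and 7 of the 16 calls were kept, against 12 with classes from a score (Satb1 at 0.77). With cluster 6 alone Ifitm1 (1.56), Tmem37 (1.51), Ly6c1 (1.29) and Igfbp4 (-2.04) did not pass, and with cluster 7 alone Sorcs2 (1.76), Slc35d1 (1.34), Plac8 (-2.59) and Mir155hg (-1.86) did not. Slc35d1 did not pass with classes from a score either (0.17). Among thinned cells the share with a UMI of Ifitm1 was 9.00% at 64 h and 8.89% at 128 h, against 1.67% and 1.82% in the PBS arms. In activated-like cells it was 11.7% and 13.5%, against 2 of 112 and 2 of 144 cells in the PBS arms. In resting-like cells it was 5.28% and 5.95%, against 2.15% and 1.61%. The fold changes of Ifitm1 thus compare a minority of cells with a PBS level near the floor.

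**Figure D4:**
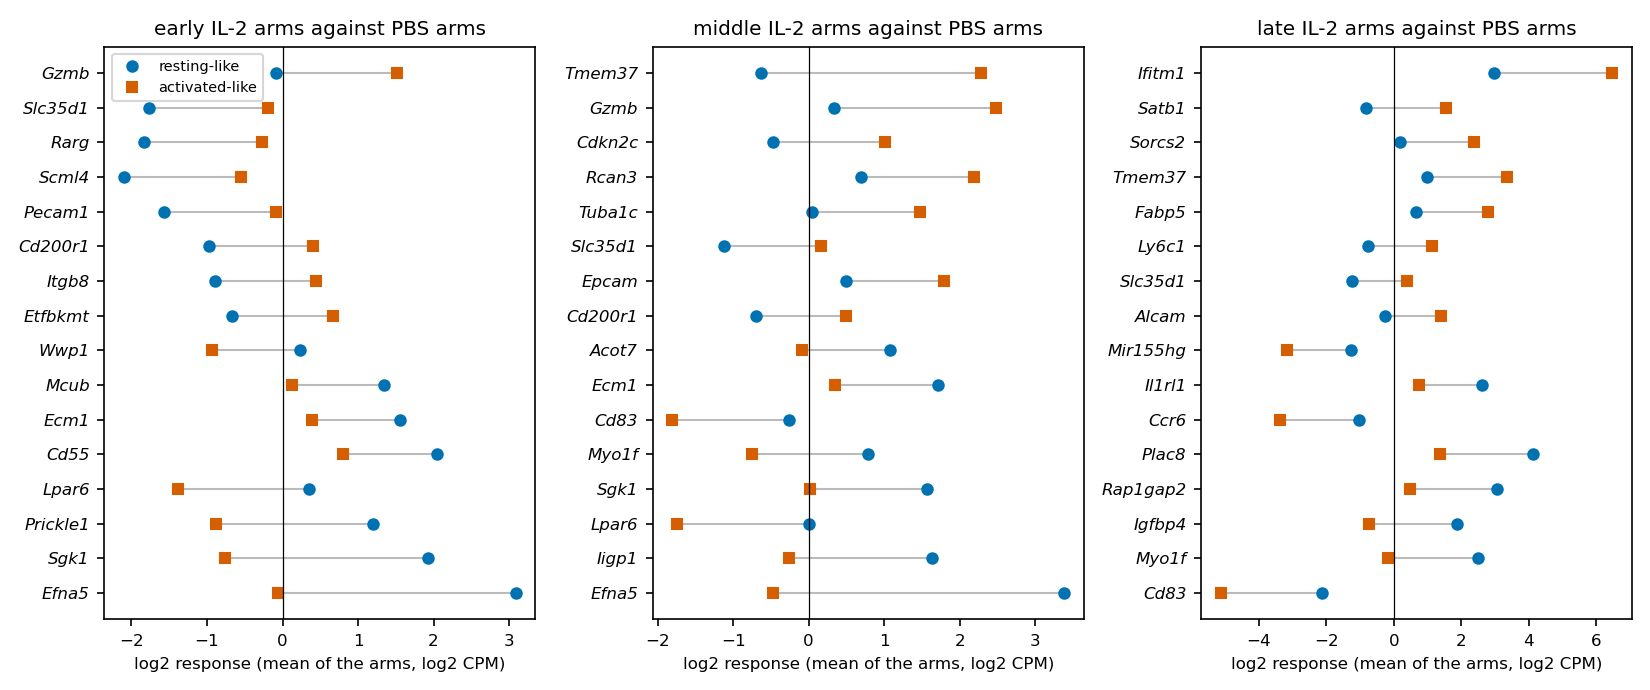
Log2 response to IL-2 relative to the PBS arms (horizontal axis) in resting-like (blue circles) and activated-like cells (orange squares) for the 16 named genes of each window (vertical axis). In the late window Ifitm1 stood at 6.49 in activated-like and 2.98 in resting-like cells, and Cd83 at -5.13 and -2.11. A UMI of Ifitm1 was found in 2 of 112 and 2 of 144 thinned activated-like cells of the PBS arms, so its reference lies near the floor.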

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

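The tests of the 2 h arm, of cells with no cell cycle UMIs at 64 h and of the 2 classes moving towards each other's level, and the sums at matched depth, were chosen after the results were seen. The sums with single clusters were added after the data were seen, but with their bounds written before their result. Tested differences between time windows or between cell classes under the same contrast come first. The UMIs per cell at 64 h and the 2 h arm are values of single arms, which were not tested against other arms.

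Between the middle and the early arms 104 genes were higher and 55 lower. The named genes differed by a log2 fold of 2.20 (Mcm3), 2.13 (Dtx1), 2.02 (Hells), 1.98 (Mcm5), 1.79 (Plac8), 1.58 (Chaf1b), 1.55 (Drc1) and 1.46 (Mcm6). On the lower side stood -1.36 (Tent5a), -1.20 (Adam19), -0.95 (Klf6), -0.89 (P2ry10), -0.89 (Spred1), -0.86 (Fnip1), -0.84 (Clint1) and -0.80 (Rgs1). The 6 arms allow 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 104 and 55 genes and the highest other split 0 and 0 with edgeR, or up to 821 and 785 against 1678 and 1048 at an unadjusted p under 0.05. Each time point is 1 arm of an unstated number of animals, so time since treatment stays open as untested, beside other differences between arms or animals.

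Between the late and the middle arms 633 genes were higher and 523 lower. The named genes differed by 5.29 (Ifitm1), 4.11 (Gzma), 3.08 (Ifitm2), 2.66 (Lgals7), 2.46 (Gzmb), 2.43 (Nckap5), 2.39 (Frmd5) and 2.33 (Ifitm3). On the lower side stood -2.40 (Cd83), -2.05 (Gcsh), -1.77 (St8sia6), -1.72 (Mettl1), -1.58 (Rragd), -1.55 (Gpr83), -1.54 (Myb) and -1.41 (Smyd2).

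The response to IL-2 differed between activated-like and resting-like cells for 52 genes early, 52 in the middle window and 304 late. The early differences were 1.65 (Gzmb), 1.64 (Slc35d1), 1.60 (Rarg), 1.59 (Scml4), 1.46 (Pecam1), 1.40 (Cd200r1), 1.38 (Itgb8), 1.37 (Etfbkmt), -3.59 (Efna5), -2.71 (Sgk1), -2.01 (Prickle1), -1.71 (Lpar6), -1.28 (Cd55), -1.22 (Ecm1), -1.20 (Mcub) and -1.15 (Wwp1). In the middle window they were 3.29 (Tmem37), 2.14 (Gzmb), 1.55 (Cdkn2c), 1.55 (Rcan3), 1.41 (Tuba1c), 1.32 (Slc35d1), 1.31 (Epcam), 1.22 (Cd200r1), -4.38 (Efna5), -1.86 (Iigp1), -1.77 (Lpar6), -1.64 (Sgk1), -1.58 (Myo1f), -1.50 (Cd83), -1.35 (Ecm1) and -1.16 (Acot7). Late they were 3.49 (Ifitm1), 2.37 (Satb1), 2.26 (Sorcs2), 2.24 (Tmem37), 2.14 (Fabp5), 1.73 (Ly6c1), 1.66 (Slc35d1), 1.63 (Alcam), -3.09 (Cd83), -2.74 (Myo1f), -2.73 (Igfbp4), -2.72 (Rap1gap2), -2.68 (Plac8), -2.29 (Ccr6), -2.21 (Il1rl1) and -2.10 (Mir155hg). For the difference of the classes over all arms, 1 of 60 assignments of the class within arms, the real one, gave as many as 6772 genes, and the highest other gave 3715. This decides nothing about chance, since expression defined the classes and so fixed the outcome. Expression also sorted the cells behind the differences in response, and their p-values do not account for this.

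The 304 late differences were not explained by unequal depth as a whole, since 189 of them passed the test with the same sign when resting-like sums were thinned to the depth of the activated-like sums. Nor was a change in the mix of both activated-like clusters the whole cause. With either cluster alone the median ratio to the full difference was 0.950 and 0.984, 303 of 304 and 301 of 302 genes had the same sign, and 145 and 112 passed the test. The mix of the resting-like clusters also differed. Cluster 2, with a median of 4433.5 UMIs per cell, held 258 of 799 and 264 of 738 such cells in the PBS arms. It held 180 of 428 at 64 h and 247 of 584 at 128 h, and a cause in this mix was not tested. A candidate explanation is that the classes moved towards each other's level: 61.2% of the genes (186 of 304) had a late difference opposite to the class difference in the middle arms, against 51.7% of all 11040 genes, barely above the bound of 60% set for it. Selection of cells, or growth of one kind of cell within a class, stays open as untested.

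Cells of the 64 h arm had a median of 13947 UMIs against 5697 and 5871 in the PBS arms. More cells in the cell cycle were not the whole cause, since among cells with no UMI of the G1/S and G2/M lists after thinning (186 at 64 h) the ratio to the PBS arms was 2.13. The test as first written, before its result was seen, used cells not thinned. There 23 such cells gave 0.977, on the side of the cell cycle explanation. That choice picks cells of few UMIs by construction (medians of 3815 and 3470 in the PBS arms) and decides nothing. Pairs of cells from the same arm read as one were not the whole cause either, since the lower quartile also lay 2.02 times higher. Larger resting or growing cells, and differences in the handling of arms before they were pooled, stay open as untested.

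The 2 h arm had 86 cells and a median of 14 UMIs of its own hashtag. On an axis of 19 genes from the later and PBS arms (0) to the 1 h and 4 h arms (1) it sat at 1.04 (0.866 to 1.20 over 2000 bootstrap draws). A mixture of the other arms would sit at 0.00255, so cells of all arms called 2 h by error were not its main content. Cells of the 1 h and 4 h arms (1.06 and 0.941, against 0.559 at 8 h) called 2 h by error cannot be told apart from true 2 h cells, since the upper bound of 1.20 includes their positions. True cells with few hashtag molecules stay open.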

How the results depend on the processing

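Sums without the deposited cluster 1, classes from deposited clusters, resting-like sums at matched depth and single activated-like clusters were alternatives chosen after the data were seen. The limits are few arms, unequal depth and, for classes, few cells. Leaving out an arm of the late or PBS window leaves 1 arm there, which is then assumed to vary like the other groups. Of 9540 values of named genes under alternatives, 7870 kept their direction and call, 1647 kept the direction without the call and 23 reversed. Where no reason is given, the cause was not tested. No paired analysis was possible because no label pairs the arms.

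With each arm left out in turn, genes higher and lower than in PBS numbered 110 to 785 and 119 to 695 early, 94 to 1828 and 131 to 1308 in the middle window, and 501 to 2059 and 427 to 1521 late. From early to middle they numbered 0 to 484 and 0 to 208, and from middle to late 215 to 722 and 142 to 720. Genes that vary over time numbered 1360 to 2562, list calls 28 to 33 and class differences over all arms 6331 to 6629. The response differed between classes for 6 to 68 genes early, 7 to 75 in the middle window and 46 to 345 late.

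With sums thinned to the smallest, fewer UMIs gave 202 higher and 212 lower genes early, 497 and 373 in the middle window and 485 and 313 late. From early to middle 157 were higher, from middle to late 146 and 117, and 843 varied over time. Classes differed for 834 genes over all arms and in response for 0 early, 1 in the middle window and 6 late (edgeR, with 54 higher and 50 lower, 62 and 61, and 61 and 100 at an unadjusted p under 0.05). Thinned sums left 7972 genes to test for windows and 1713 for classes, against 14465 and 11040 in the main fits. These lower counts are therefore also counts over fewer genes. With 86 cells per arm, fewer cells gave 112 and 156 early, 261 and 249 in the middle window, 383 and 301 late, 50 and 22 from early to middle, 122 and 96 from middle to late, and 660 over time. That fit tested 8295 genes. With no filter, more genes were tested, with 1012 and 898 early, 1035 and 338 from early to middle, 1244 and 1004 from middle to late, 4035 over time, and 90 early and 107 middle class differences in response. Without cycling cells, which are picked by genes of the lists, 968 were higher and 742 lower in the middle window and 52 higher from early to middle. DESeq2's Wald test gave 517 and 270 from early to middle and 31 early and 121 late class differences in response, and its size factors 92 lower from early to middle. The spline gave 3943 genes over time. Without the deposited cluster 1, 188 and 115 genes differed from early to middle. With an estimated correlation 0 list calls were left by camera, while edgeR's calls of single members do not use it.

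With classes from a score 15, 31 and 601 genes differed in response early, in the middle window and late. With cluster 6 alone 4406 genes differed over all arms and 194 in late response, and with cluster 7 alone 32 in early and 180 in late response. In these class alternatives sums hold other or fewer cells.

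With a minimum of 2 UMIs the G2/M share was 8.47% at 1 h, 12.2% at 2 h, 5.72% at 4 h, 6.23% at 8 h, 10.3% at 16 h, 15.3% at 24 h, 38.2% at 64 h, 17.3% at 128 h and 9.27% and 9.24% in the PBS arms. With 5 UMIs it was 1.04% at 1 h, 0.507% at 4 h, 0.228% at 8 h, 1.99% at 16 h, 6.32% at 24 h, 23.5% at 64 h, 5.03% at 128 h and 0.532% and 0.758% in the PBS arms. In cells not thinned it was 9.49% at 1 h, 8.12% at 4 h, 12.9% at 8 h, 21.2% at 16 h, 24.7% at 24 h, 55.5% at 64 h, 33.6% at 128 h and 8.40% and 10.5% in the PBS arms. By construction a lower minimum or a higher depth counts more cells. Above the 90th percentile of the PBS cells the STAT5 score placed 49.7% at 1 h, 55.4% at 2 h, 44.9% at 4 h, 28.4% at 8 h, 29.5% at 16 h, 32.7% at 24 h, 37.6% at 64 h, 32.2% at 128 h and 11.5% and 6.67% in the PBS arms. Above the 99th it placed 8.95%, 12.2%, 6.30%, 3.65%, 4.43%, 5.47%, 6.00%, 3.86%, 0.988% and 0.303% of the same arms in this order. With 1 CPM added the STAT5 list stood at 0.90 at 1 h, 0.77 at 4 h, 0.64 at 8 h, 0.54 at 16 h, 0.56 at 24 h, 0.56 at 64 h and 0.50 at 128 h.

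Values that reversed were, without cycling cells, those of Cdc6 in the middle window (-0.26), and late those of Mcm3 (-0.29), Mcm5 (-0.17), Cdc6 (-0.23), Rrm1 (-0.37), Rrm2 (-0.16), Gins2 (-0.42), Cdc45 (-0.50), Cdc20 (-0.48), Aurka (-0.56), Hmmr (-0.0709), Cks2 (-0.0868), Ccna2 (-0.47) and Tacc3 (-0.00774), genes by which those cells are picked. With 86 cells per arm Nop2 (-0.25), Ndufs2 (-0.000417) and Dusp1 (-0.33) in the middle window and Slc1a5 late (-0.0392) reversed. Mvk reversed late with arms thinned (-0.60). With classes from deposited clusters the differences in response of Slc35d1 (-0.14 middle, -0.39 late), Myo1f (0.000603 middle) and Ccr6 (0.97 late) reversed. Smaller sums are less precise. Depth limits genes of few UMIs and the 2 h arm the most.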

Other observations

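The genes below were chosen after their values were seen. Lif, a cytokine gene of the IL-6 family, rose in each window (2.05, 2.71 and 1.88), and so did Osm, another gene of that family (1.66, 1.57 and 1.29). The calls of Osm held whichever arm was left out, but the late one was lost with every arm thinned to the smallest (1.06) or with 86 cells per arm (1.29). Those of Lif were lost early without 4 h (1.71) or either PBS arm (2.06 and 2.05) and late without 64 h (1.13) or either PBS arm (1.88 and 1.88). Il10, an anti-inflammatory cytokine gene, stood at -0.35 early (adjusted p = 0.864), at 1.74 in the middle window (adjusted p = 0.102) and rose late (2.84 ± 0.71, adjusted p = 0.0163), a call that was lost without 128 h (2.04), PBS 2 h (3.47), PBS 128 h (2.41) or cycling cells (2.29). Tigit and Havcr2, genes of inhibitory receptors, stood at 0.24 (adjusted p = 0.679) and 1.28 (adjusted p = 0.0503) early, -0.00666 (adjusted p = 0.990) and 1.09 (adjusted p = 0.0439) in the middle window and 1.70 ± 0.29 and 1.97 ± 0.36 late. The late calls of Tigit and Havcr2 held whichever arm was left out, and that of Tigit was lost with 86 cells per arm (1.958). Lif, Il10 and Havcr2 had no value with arms thinned or with 86 cells per arm, and Tigit had none with arms thinned. The middle call of Havcr2 was lost without 8 h (1.08), 16 h (1.15), 24 h (1.03), PBS 2 h (1.12) or PBS 128 h (1.05), and without cells of other types (1.01). By the direct test Tigit was higher in the late than in the middle arms (1.70 ± 0.25, adjusted p = 0.00236), whichever arm was left out but not with 86 cells per arm (1.89). Differences from the middle to the late window did not pass for Havcr2 (0.88, adjusted p = 0.0835), Il10 (1.10, adjusted p = 0.215), Lif (-0.84, adjusted p = 0.124) and Osm (-0.28, adjusted p = 0.296), and neither did those of the 5 genes from the early to the middle window (lowest adjusted p = 0.141).

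A few cells held most UMIs of some genes that no T cell should make in quantity. In the 16 h arm 1 cell held 4560 of 4695 UMIs of the hemoglobin gene Hbb-bs, in the PBS 128 h arm 1 cell held 1745 of 1832, and in the 1 h arm 1 cell held 1970 of 2097 UMIs of the immunoglobulin gene Igkc. The deposited cluster 1 held 1911 cells with a median of 2785 UMIs.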
